A study of Mus musculus with 9 samples.

How the data were processed

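RNA was measured on 9 Affymetrix whole-transcript arrays from RN2 cells, a mouse acute myeloid leukaemia line driven by the MLL-AF9 fusion and an activated Nras allele. Per the labels' protocols, cells carried a doxycycline-inducible short hairpin RNA and received 1 ug/ml doxycycline for 96 h. Total RNA was purified on columns, and fragmented cDNA was end-labelled with biotin. The hairpins Brg1sh_3232, Brg1sh_3364 and Brg1sh_4935 target Brg1, the protein encoded by Smarca4, and have 2 arrays each. The control hairpin targets Renilla luciferase, which mouse cells lack, and has 3 arrays. The labels give the control arrays a cell line name with an extra term that the knockdown arrays do not carry, so this difference in name runs with the comparison.

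The deposited values are log2 expression per probe set, 1 column per array, made with RMA per the submitters' processing notes. RMA subtracts background, equalises the distributions of the arrays by quantiles and summarises the probes of a set. The RMA version, the software and the genome build of the array are not given in the sources used here. Scanner files were not used here, so background correction, scan date and slide could not be varied or tested, and no detection calls were used. The number of arrays limits the precision of every value. Array medians lay between 7.39 and 7.49 over 34760 probe sets, and no value was missing. Correlations across probe sets were 0.996 to 0.997 within a group, 0.992 to 0.995 between different hairpins and 0.989 to 0.994 between a hairpin and the control. No pair of arrays was the same throughout: between 1239 and 1906 of the 34760 values were equal as deposited, with no tolerance.

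Probe sets were named from the platform annotation. Of these, 21640 had 1 gene symbol, 1321 had several and were not named, and 11799 had none. Entrez identifiers placed 21553 of the single-symbol probe sets in a RefSeq gene table of assembly GRCm38.p6, which altered 0 symbols. A gene with several probe sets, as 954 had, was represented by the one with the highest mean over all arrays. This left 19937 genes, with no filter on dim genes. No coordinates are given because the build of the array is not named.

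Group means were fitted to all 9 arrays with limma 3.58.1 in R 4.3.3, so that all groups shared 1 estimate of the spread. Moderated statistics from eBayes had 5 residual and 3.85 prior degrees of freedom. The main contrast was the mean of the 3 hairpin groups, equally weighted, minus the control. Each hairpin was also set against the control and against each other hairpin, and a moderated F test covered differences among the hairpins. Tests were two-sided. Genes were called at a Benjamini-Hochberg adjusted p below 0.05. Errors beside log2 changes are standard errors (SE) of the fit, and levels are given as mean ± standard deviation (SD). Nothing states that replicate arrays came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The control group serves all 3 hairpins, and overlaps were therefore set beside 20 simulations of unchanged groups measured against the same kind of shared controls.

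Gene lists, 23 in all, were fixed before the data were examined, as were the tests of the comparisons, the alternatives listed below except 1, and the rule for naming genes. Some tests of explanations and of gene families came later and are named as such where they stand. Of 695 list entries, 639 had a gene of their own on the array; the others were not analysed here. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 23 lists. Camera with a correlation estimated from the arrays, camera on ranks and fry served as alternatives. Members of each list were counted over all genes tested and adjusted over the list alone. The naming rule took 11 fixed genes (Smarca4, Myc, Pvt1, Hoxa9, Meis1, Myb, Kit, Itgam, Cd14, Csf1r and Smarca2). It added the 12 largest rises and 12 largest falls among called genes whose 6 knockdown arrays all lay on that side of all 3 controls. It left out from these the predicted models, clone and small RNA names, olfactory and vomeronasal receptors and antigen receptor segments. It also took up to 4 members per list with the smallest p, and the 6 genes with the smallest F test p under the same exclusions. A gene that several parts named counted under each.

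Alternatives were a further quantile normalization, centring each array on its median, leaving out genes below the median level, averaging all probe sets of a gene and testing every row of the deposited values. Others were a trended robust eBayes, array weights, the replicate number as a block, stricter thresholds, leaving out each array or each hairpin, and fits with other treatments of the hairpins. Hairpins were treated as absent, as 3 single replicates, as a random block or 1 at a time. An exact permutation of list means was added after seeing the data.

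The fit was tested on simulated data with the real gene means and spreads, 19937 genes and 200 changed genes. For the mean contrast it recovered 96%, 98%, 100% and 100% of 50 genes each at log2 changes of 0.3, 0.5, 1 and 2, with 5 false among 202 calls. For Brg1sh_3364 against control the shares were 54%, 96%, 100% and 100%, with 8 false among 183 calls. The F test recovered 100% of 200 genes at a log2 change of 1, with 12 false among 212 calls. Camera recovered the 1 list shifted by 0.3 and called 0 of 22 others, but the simulated genes were independent, so this did not test correlated lists. Figures were drawn with matplotlib 3.10.9.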

Results

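Expression was measured on 9 arrays of RN2 mouse leukaemia cells after 96 h of hairpin induction. The series set out to map the transcription network that lies downstream of Brg1, the ATPase subunit of the SWI/SNF chromatin remodelling complex. The hairpins Brg1sh_3232, Brg1sh_3364 and Brg1sh_4935 against Brg1 had 2 arrays each, and the hairpin against Renilla luciferase had 3. The deposited values are log2 expression after RMA, with array medians between 7.39 and 7.49.

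The targeted gene was examined first in every array. Smarca4 (probe set 10583697, Entrez 20586), which encodes Brg1, stood at 10.77 ± 0.08 (SD, n = 6) in knockdown arrays and 11.79 ± 0.01 (SD, n = 3) in controls. It fell by 1.01 on the log2 scale (SE 0.05, limma adjusted p = 2.22e-06), and all 6 knockdown arrays lay below all 3 controls. The remaining level was 50.0% of control with Brg1sh_3232 (95% interval 45.2 to 55.4), 50.3% with Brg1sh_3364 (45.4 to 55.7) and 48.2% with Brg1sh_4935 (43.5 to 53.3). The hairpins did not differ in this by the F test (adjusted p = 0.802). Array background compresses such values, so they are levels of probe signal.

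Among 28 measured SWI/SNF subunits, 6 rose and 3 fell, with the same counts adjusted over the list alone. The falls included the target Smarca4. The balance was not stable: 3 rose and 5 fell with arrays centred on their medians, and 6 rose and 5 fell after a further quantile normalization. Bcl7b rose by 0.28 (SE 0.04, adjusted p = 0.000362), Arid1b by 0.27 (SE 0.05, adjusted p = 0.00273) and Arid1a by 0.23 (SE 0.04, adjusted p = 0.0032). Smarca2, which encodes the alternative ATPase Brm, had a log2 change of 0.11 (SE 0.05, adjusted p = 0.142). The list as a whole was not called by camera (adjusted p = 0.788). Its median was -0.01 and its mean -0.01, while camera gave the direction as up and fry as down.

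**Figure D1:**
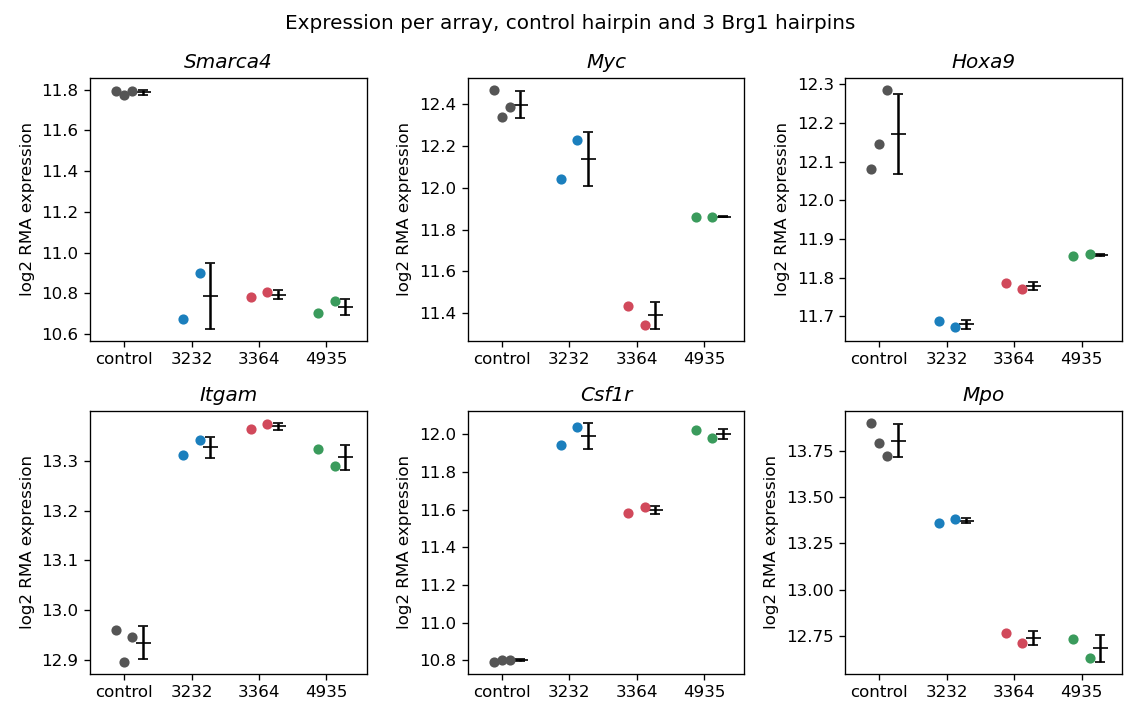
Log2 RMA expression of 6 genes on each array, for the control hairpin (3 arrays) and the Brg1 hairpins Brg1sh_3232, Brg1sh_3364 and Brg1sh_4935 (2 arrays each). Points are arrays, and the black bar beside each group is its mean with the SD. Smarca4 lies near 11.79 in controls and near 10.77 in all knockdown groups, whereas Myc is lowest with Brg1sh_3364.

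Across the mean of the 3 hairpins, Cpa3, C3ar1 and Cd200r3 had the largest rises among genes that the naming rule admits. Cpa3, a mast cell carboxypeptidase, rose by 3.46 (SE 0.25), from 9.37 ± 0.74 (SD, n = 3) to 12.83 ± 0.44 (SD, n = 6). C3ar1, the receptor for complement fragment C3a, rose by 3.41 (SE 0.17) and Itgax, the CD11c integrin chain, by 3.03 (SE 0.16). Cd200r3 and Cd200r4, of the CD200 receptor family, rose by 3.15 (SE 0.16) and 2.49 (SE 0.13). Lgmn, a lysosomal protease, rose by 2.77 (SE 0.11), and Eif2s3y, a Y-linked translation initiation factor subunit, by 2.89 (SE 0.09). F2rl2, a thrombin receptor, rose by 2.75 (SE 0.20), Eya1, a transcriptional cofactor, by 2.44 (SE 0.07) and the kinase gene Camk1d by 2.44 (SE 0.10). Mc5r, a melanocortin receptor, rose by 2.22 (SE 0.18), and Angpt1, a ligand of the Tie2 receptor, by 2.20 (SE 0.06). Adjusted p for these 12 genes ranged from 1.74e-07 for Angpt1 to 3.03e-05 for Mc5r.

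Under the same rule Car4, Hao1 and Nkg7 had the largest falls. Car4, a membrane carbonic anhydrase, fell by 3.03 (SE 0.09), from 11.70 ± 0.09 (SD, n = 3) to 8.67 ± 1.17 (SD, n = 6). Hao1, a hydroxyacid oxidase, fell by 2.63 (SE 0.15), and Chpt1, a choline phosphotransferase, by 1.92 (SE 0.06). Fads2, a fatty acid desaturase, fell by 2.41 (SE 0.15). Hdc, which makes histamine, fell by 1.71 (SE 0.06) and the carboxylesterase gene Ces1d by 1.65 (SE 0.08). Nkg7, a cytotoxic granule protein, fell by 2.56 (SE 0.22), the tetraspanin gene Tspan2 by 2.39 (SE 0.09) and the serpin gene Serpinb10 by 2.13 (SE 0.10). Cnn3, a calponin, fell by 1.96 (SE 0.10), Atp1b1, a sodium pump subunit, by 1.57 (SE 0.12). The mucin gene Muc13 was 2.83-fold lower (SE 0.05 on the log2 scale). Adjusted p for these 12 genes ranged from 1.88e-07 for Car4 to 3.56e-05 for Nkg7.

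In all, 5635 of 19937 genes were called (28.3%), of which 2652 rose and 2983 fell. Most changes were small: the median absolute log2 change of called genes was 0.29, and 143 rose and 52 fell at least 2-fold. Among called genes, 1950 rises and 2238 falls had all 6 knockdown arrays apart from all 3 controls; over all genes 4552 were apart, where chance gives 2.38%. Higher calls made up 47.1%, against 36.5% when arrays were centred on their medians and 45.4% after a further quantile normalization. With the 3 hairpin means as replicates the count was 2816, and with the hairpin as a random block it was 2557.

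**Figure D2:**
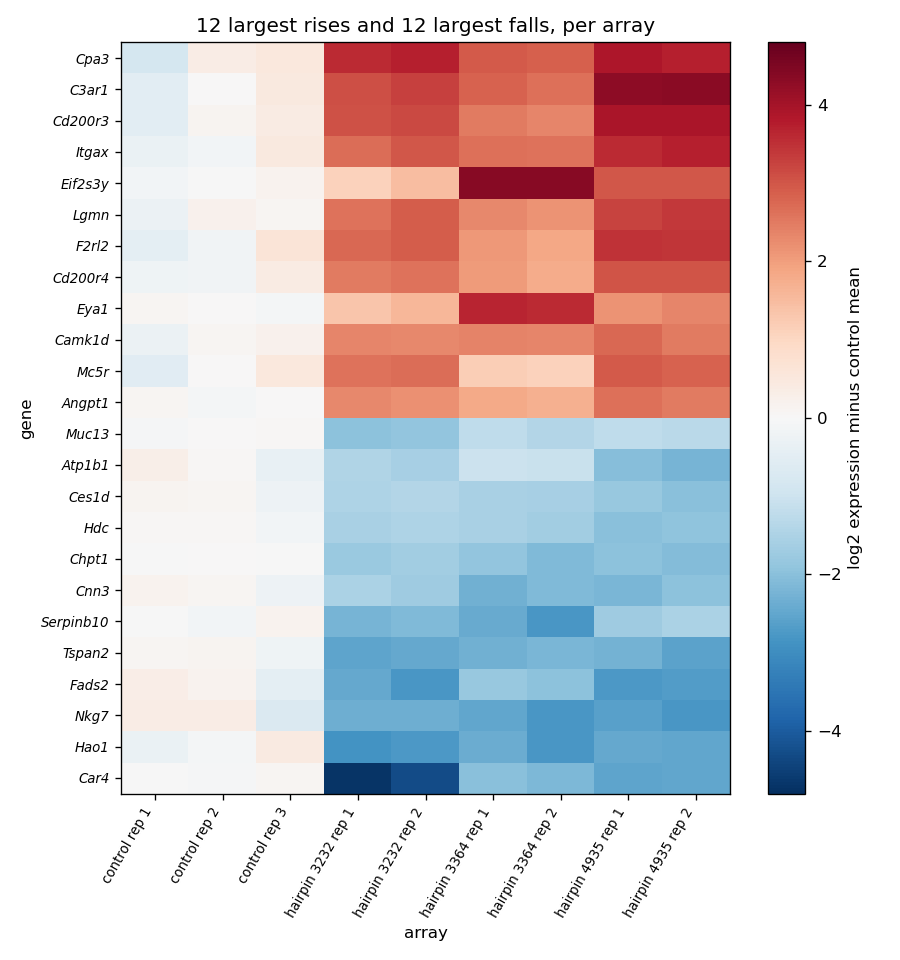
Log2 expression minus the control mean for the 12 largest rises and 12 largest falls (rows) on the 9 arrays (columns), with red above and blue below the control mean. Values run from -4.71 to 4.39, and all 6 knockdown arrays lie on one side of the 3 controls in each row.

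Genes tied to the leukaemic and progenitor state moved in both directions. Myc (probe set 10424400), the growth-driving transcription factor, fell by 0.60 (SE 0.05, adjusted p = 3.49e-05), from 12.40 ± 0.06 (SD, n = 3) to 11.80 ± 0.35 (SD, n = 6). Pvt1, the noncoding gene beside Myc, fell by 0.53 (SE 0.10, adjusted p = 0.00467), though its second probe set had a log2 change of 0.02. Hoxa9, a homeobox gene kept on by MLL fusions, fell by 0.40 (SE 0.05, adjusted p = 0.000229), while its partner Meis1 rose by 0.22 (SE 0.06, adjusted p = 0.0153). Myb had a log2 change of -0.08 (SE 0.03, adjusted p = 0.106) and Kit one of 0.02 (SE 0.04, adjusted p = 0.741). With the 3 hairpin means as replicates the calls of Myc (adjusted p = 0.0735), Pvt1 (0.105) and Meis1 (0.182) were lost. Without Brg1sh_3364 those of Pvt1 (0.0704) and Meis1 (0.162) were lost too.

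Of 38 measured genes on the list for leukaemia and progenitor self-renewal, 11 rose and 7 fell, with the same counts adjusted over the list alone. Besides Eya1, the transcription factor gene Ikzf2 rose by 1.10 (SE 0.05) and Jmjd1c, of the JmjC demethylase family, by 0.27 (SE 0.03). The list was not called by camera (adjusted p = 0.184), but fry called it as higher (adjusted p = 0.00565). By hairpin, camera gave adjusted p = 0.35 for Brg1sh_3232, 0.419 for Brg1sh_3364 and 0.0233 for Brg1sh_4935.

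Most measured genes on the lists for ribosome production and anabolic metabolism fell. All 43 measured genes of ribosome biogenesis fell, also when adjusted over the list alone, with a median log2 change of -0.43. Rrs1 fell by 0.81 (SE 0.07), Polr1e, an RNA polymerase I subunit, by 0.64 (SE 0.05), Rrp1b by 0.59 (SE 0.06) and Mybbp1a by 0.51 (SE 0.04). The list's camera adjusted p was 6.17e-21, and adjusted p = 0.158 with an estimated correlation. For nucleotide, amino acid and polyamine synthesis, 29 of 30 genes fell under both adjustments and 0 rose. Phgdh and Psat1, of serine synthesis, fell by 1.20 (SE 0.05) and 0.57 (SE 0.03), Tfrc, the transferrin receptor, by 1.13 (SE 0.06) and the folate enzyme gene Mthfd1 by 0.61 (SE 0.04). Camera gave an adjusted p of 5.64e-17 for this list, and adjusted p = 0.121 with an estimated correlation. Of 19 cholesterol synthesis genes 14 fell and 0 rose (15 fell adjusted over the list alone). Sqle fell by 0.79 (SE 0.06), Cyp51 by 0.67 (SE 0.08), Hsd17b7 by 0.46 (SE 0.05) and Idi1 by 0.44 (SE 0.05; -0.79 on its second probe set). Their list had an adjusted p of 3.26e-08, and adjusted p = 0.157 with an estimated correlation.

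Most measured genes of DNA replication and mitosis fell, and of the cell cycle inhibitors more rose than fell. Of 42 DNA replication genes 33 fell and 1 rose (35 and 1 adjusted over the list alone). Orc1, of the origin recognition complex, fell by 0.81 (SE 0.06), the phosphatase gene Cdc25a by 0.58 (SE 0.04), Gins1, of the replicative helicase, by 0.58 (SE 0.04) and Tyms, thymidylate synthase, by 0.37 (SE 0.03). The replication list had an adjusted p of 9.12e-14, and adjusted p = 0.0958 with an estimated correlation. Of 34 mitosis genes 28 fell and 0 rose (30 fell adjusted over the list alone). By hairpin, 28 fell with Brg1sh_3232, 12 with Brg1sh_3364 and 28 with Brg1sh_4935, with medians of -0.336, -0.135 and -0.293. The mitotic kinase genes Aurka, Ttk and Cdk1 fell by 0.53 (SE 0.04), 0.43 (SE 0.04) and 0.29 (SE 0.03), and Cdc20 by 0.42 (SE 0.04). The mitosis list had an adjusted p of 1.41e-13, and adjusted p = 0.158 with an estimated correlation. Of 17 cell cycle inhibitors 10 rose and 0 fell (12 and 1 adjusted over the list alone). Cdkn1a had no gene of its own on the array, so these counts leave it out. The inhibitor Cdkn2b rose by 0.69 (SE 0.08), the antiproliferative Btg1 by 0.67 (SE 0.04), the Max partner Mxd4 by 0.54 (SE 0.04) and Ccng2 by 0.40 (SE 0.05). The call of Ccng2 was lost with the 3 hairpin means as replicates (adjusted p = 0.124). The inhibitor list had an adjusted p of 1.32e-06, and adjusted p = 0.0958 with an estimated correlation.

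Most measured markers of the macrophage and monocyte lineage rose. Of 49 measured members 31 rose and 3 fell (33 and 4 adjusted over the list alone). The chemokine receptor gene Cx3cr1 rose by 1.92 (SE 0.05) and Csf1r, the receptor for the macrophage growth factor, by 1.06 (SE 0.04). Adgre1, the F4/80 antigen, rose by 1.05 (SE 0.05), Mpeg1, a perforin-like protein, by 0.91 (SE 0.04) and Itgam, the CD11b integrin chain, by 0.40 (SE 0.03, adjusted p = 3.43e-05). Cd14, the endotoxin co-receptor, rose by 0.59 (SE 0.06, adjusted p = 9.8e-05), a call lost with hairpin means as replicates (adjusted p = 0.052). The macrophage list had an adjusted p of 4.28e-11, and adjusted p = 0.121 with an estimated correlation. Of 46 lysosome genes 30 rose and 2 fell (31 and 3 adjusted over the list alone). Besides Lgmn, the lysosomal hydrolase genes Ids and Idua rose by 1.75 (SE 0.06) and 0.92 (SE 0.05), and Mitf, a transcription factor, by 0.85 (SE 0.04; -0.04 on its second probe set). The lysosome list had an adjusted p of 2.97e-10, and adjusted p = 0.0958 with an estimated correlation.

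Early and late neutrophil genes were counted apart, and the difference between these lists was not tested. Of 11 genes of primary granules and their regulators 7 fell and 1 rose, the same counts as adjusted over the list alone. Cst7 fell by 1.22 (SE 0.06), Mpo, myeloperoxidase, by 0.87 (SE 0.05), the regulator gene Cebpa by 0.61 (SE 0.04) and Prtn3, proteinase 3, by 0.56 (SE 0.05). The call of Prtn3 was lost with hairpin means as replicates (adjusted p = 0.0674). The primary granule list had an adjusted p of 0.000516, and adjusted p = 0.279 with an estimated correlation. By hairpin, camera at the preset correlation did not call it with Brg1sh_3232 (adjusted p = 0.0517), but did with Brg1sh_3364 (0.000524) and Brg1sh_4935 (1.34e-05). Of 29 late neutrophil genes 14 rose and 4 fell (15 and 5 adjusted over the list alone). The collagenase gene Mmp8 rose by 1.84 (SE 0.13), the histone citrullinating enzyme gene Padi4 by 1.00 (SE 0.05), Mmp9 by 0.92 (SE 0.07) and Trem1 by 0.70 (SE 0.05). That of Padi4 was lost with hairpin means as replicates (adjusted p = 0.0874). The late list had an adjusted p of 0.00105, and adjusted p = 0.544 with an estimated correlation. Without Brg1sh_3364 the camera value was 0.122, and an exact permutation added after seeing the data gave 0.205. By hairpin, camera at the preset correlation called it with Brg1sh_3364 (adjusted p = 3.78e-08), but not with Brg1sh_3232 (0.312) or Brg1sh_4935 (0.073).

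Markers of other blood cell types were not called as lists by camera at the preset correlation. Of 20 dendritic cell genes 3 rose and 1 fell (adjusted p = 0.207): the regulator gene Id2 rose by 0.42 (SE 0.04), Klrd1 by 0.45 (SE 0.06) and Ccl17 by 0.17 (SE 0.05), and Clec10a fell by 0.20 (SE 0.05). The last 3 lost their calls with hairpin means as replicates (Klrd1 0.0732, Ccl17 0.117 and Clec10a 0.0513). Ccl17 also lost its call without Brg1sh_3232 replicate 1 (0.0592) or 2 (0.0674), without Brg1sh_3364 replicate 1 (0.0769) and without control replicate 2 (0.0928) or 3 (0.123). The same held without Brg1sh_3364 (0.137), after a further quantile normalization (0.0714), with arrays centred on their medians (0.107) and with the replicate number as a block (0.0924). Clec10a lost its call without control replicate 2 (0.0645) or 3 (0.0714). Of 16 erythroid and megakaryocyte genes 1 rose and 0 fell (adjusted p = 0.322): Vwf rose by 0.25 (SE 0.05, adjusted p = 0.00379). Log2 changes were 0.17 for Tfr2 (SE 0.06), 0.12 for Itga2b (SE 0.05) and 0.10 for Ppbp (SE 0.06). Tfr2 was called without Brg1sh_3364 replicate 2 (adjusted p = 0.0154), without Brg1sh_3232 (0.048) and without Brg1sh_4935 (0.0431). Of 17 mast cell, basophil and eosinophil genes 3 rose and 4 fell (adjusted p = 0.93). Beside Cpa3 and Hdc, which moved in opposite directions, Prg2, an eosinophil granule protein, rose by 1.73 (SE 0.05) and the basophil protease gene Mcpt8 fell by 0.39 (SE 0.07). Both were lost with hairpin means as replicates (Prg2 0.134 and Mcpt8 0.131). Of 27 lymphoid genes 1 rose and 3 fell (adjusted p = 0.985). Il7r rose by 1.18 (SE 0.14), while besides Nkg7 the B cell receptor chain Cd79b fell by 0.77 (SE 0.07) and perforin, Prf1, by 0.51 (SE 0.04). Il7r lost its call with hairpin means as replicates (adjusted p = 0.0926). For these 4 lists the counts adjusted over the list alone were the same. The lymphoid median was 0.02 and its mean -0.08, with a test direction of down.

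Antigen presentation genes split: of 17 measured, 5 rose and 3 fell (5 and 4 adjusted over the list alone). The list was not called by camera (adjusted p = 0.705, median -0.00 and mean 0.03). Its members H2-K1, H2-D1, H2-T23, H2-DMb1 and H2-DMb2 had no gene of their own on the array, so the counts leave them out. Cd74, the invariant chain, rose by 0.62 (SE 0.06), Tapbp by 0.43 (SE 0.04) and the peptide transporter gene Tap1 by 0.33 (SE 0.05), while the class II gene H2-Ab1 fell by 0.87 (SE 0.07). Of 34 interferon response genes 20 rose and 5 fell (21 and 6 adjusted over the list alone). Usp18, a deconjugase of the ISG15 modifier, rose by 1.90 (SE 0.09), the regulator genes Irf7 and Irf9 by 1.20 (SE 0.06) and 1.17 (SE 0.05), and Oasl2 by 0.38 (SE 0.04). The call of Oasl2 was lost with hairpin means as replicates (adjusted p = 0.187). The interferon list had an adjusted p of 1.06e-05, and adjusted p = 0.204 with an estimated correlation. Of 33 inflammatory cytokines and NF-kB targets 17 rose and 1 fell (19 and 1 adjusted over the list alone). The inhibitor gene Tnfaip3 rose by 0.67 (SE 0.03), Il1b by 0.61 (SE 0.04), Tnf by 0.50 (SE 0.03) and the adhesion gene Icam1 by 0.47 (SE 0.03). The inflammatory list had an adjusted p of 3.46e-07, and adjusted p = 0.106 with an estimated correlation.

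Of 23 genes of the integrated stress response 13 fell and 2 rose (13 and 3 adjusted over the list alone). Those that fell included the amino acid enzymes Cth at 1.31 (SE 0.11) and Phgdh and Psat1 above, and the secreted Stc2 fell by 0.92 (SE 0.05). This list had an adjusted p of 0.000595, and adjusted p = 0.106 with an estimated correlation. Of 20 unfolded protein response genes 10 fell and 0 rose (12 fell adjusted over the list alone). Pdia6 and Pdia4, protein disulphide isomerases, fell by 0.39 (SE 0.04) and 0.22 (SE 0.03), Sdf2l1 by 0.25 (SE 0.04) and Creld2 by 0.20 (SE 0.03). It had an adjusted p of 0.00105, and adjusted p = 0.109 with an estimated correlation. Of 27 p53 targets and apoptosis genes 9 rose and 5 fell (10 and 5 adjusted over the list alone). Cdkn1a, Bax and Gdf15 had no gene of their own on the array, so these counts leave them out. Trp53inp1 rose by 0.82 (SE 0.04), Sesn1 by 0.65 (SE 0.04), the cell death gene Bid by 0.60 (SE 0.04) and Bcl2l1, a survival gene, by 0.45 (SE 0.04). The p53 list had an adjusted p of 0.0179, and adjusted p = 0.283 with an estimated correlation. It was 0.0504 without Brg1sh_3364 replicate 1 and 0.0534 without control replicate 1. By hairpin, camera at the preset correlation gave adjusted p = 0.0639 for Brg1sh_3232, 0.0274 for Brg1sh_3364 and 0.0168 for Brg1sh_4935. Of 19 glycolysis genes 3 rose and 3 fell, also over the list alone (adjusted p = 0.788, median -0.00, mean -0.01 and test direction up). The lactate transporter gene Slc16a1 fell by 1.08 (SE 0.08), while its relative Slc16a3 rose by 0.31 (SE 0.04), Aldoc by 0.57 (SE 0.06) and the glucose transporter gene Slc2a3 by 0.44 (SE 0.05). Slc2a3 did not rise with every hairpin: its log2 change was -0.10 with Brg1sh_3232 (limma adjusted p = 0.345), 1.12 with Brg1sh_3364 and 0.31 with Brg1sh_4935. The calls of Aldoc (0.132), Slc16a3 (0.0937) and Slc2a3 (0.413) were lost with hairpin means as replicates, and that of Slc2a3 also without Brg1sh_3364 (0.274).

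**Figure D3:**
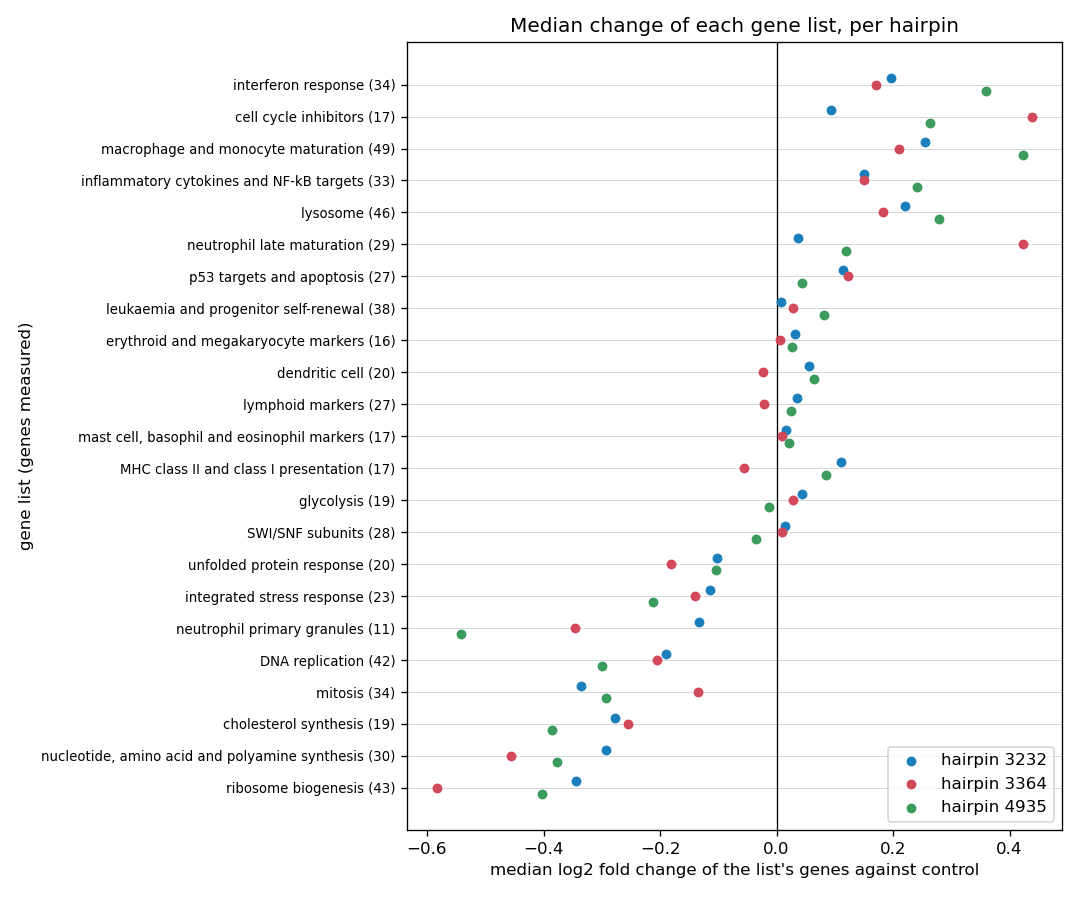
Median log2 change against control of each of the 23 gene lists (rows, with the number of genes measured), per hairpin (coloured points; Brg1sh_3232, Brg1sh_3364 and Brg1sh_4935). The ribosome biogenesis list has medians of -0.34, -0.58 and -0.40 and the macrophage list of 0.26, 0.21 and 0.42 in that order.

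By camera at the preset correlation, 15 of the 23 lists were called, 7 higher and 8 lower. With an estimated correlation 0 were called (lowest adjusted p = 0.0958), though 8 had an unadjusted p below 0.05. By fry's directional test 17 were called, which added the leukaemia (adjusted p = 0.00565) and dendritic (0.024) lists. The medians of the lists for leukaemia, dendritic, erythroid and megakaryocyte, mast cell and lymphoid genes were above 0, and turned below 0 when arrays were centred on their medians and, except for the leukaemia list, also after a further quantile normalization.

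The 3 single-hairpin comparisons ask which changes recur with independent sequences against the same target. Brg1sh_3232 called 4155 genes (1912 rose and 2243 fell), Brg1sh_3364 called 5133 (2707 and 2426) and Brg1sh_4935 called 4402 (1952 and 2450). With arrays centred on their medians, rises and falls were 2283 and 2991 for Brg1sh_3364 and 1560 and 3375 for Brg1sh_4935. After a further quantile normalization Brg1sh_3364 had 2606 and 2763. In the fit to the values as deposited, 2440 moved the same way with all 3 hairpins, 1216 up and 1224 down, and 95 did so by at least 2-fold in each. Centred arrays gave 997 up and 1519 down. Independent lists of these sizes would share 25.4 rises and 33.5 falls. Simulated unchanged groups against shared controls gave 0 in 20 simulations. With no gene changed, few pass the adjusted threshold by construction, so that 0 is no test of the overlap. At an unadjusted p below 0.05 the shared number was 3504, against a simulated mean of 61.3. Hoxa9 fell with each hairpin, by 0.49, 0.39 and 0.31 for Brg1sh_3232, Brg1sh_3364 and Brg1sh_4935, and Itgam rose by 0.39, 0.43 and 0.37. Myc fell by 0.26 (adjusted p = 0.0209), 1.01 (1.28e-05) and 0.54 (0.000452). Genes called up by one hairpin and down by another numbered 107. Across genes, which are not independent replicates, log2 changes correlated at 0.742 for Brg1sh_3232 and Brg1sh_3364, 0.871 for Brg1sh_3232 and Brg1sh_4935 and 0.783 for Brg1sh_3364 and Brg1sh_4935. Simulated unchanged groups gave 0.400, 0.401 and 0.400. Covariances were 0.0543, 0.0633 and 0.0652, against 0.0021 simulated for each pair. The 3 control arrays could not be split into sets of at least 2, and part or all of the excess may come from the shared controls. The labels give the control arrays a line name of their own, and any difference of that line would enter all 3 comparisons alike. The simulations held only the spread between arrays, so they do not measure such a difference. Single arrays weigh on the counts: Brg1sh_3232 called 2473 genes without its replicate 2 and 2475 when fitted with the control alone, and Brg1sh_4935 called 2673 without its replicate 1 and 2707 without its replicate 2.

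The hairpins were then compared with each other, which needs no control arrays for the difference itself. By the F test 2086 genes differed among them (10.5%), and 1341 of these were also called in the mean contrast. The hairpin farthest from the other two was Brg1sh_3364 for 1273 of them, Brg1sh_3232 for 483 and Brg1sh_4935 for 330. Prg2 rose by 3.34 with Brg1sh_3364 against 0.95 and 0.91 with Brg1sh_3232 and Brg1sh_4935 (F test adjusted p = 1.19e-06). Lrrk2, a kinase gene (mean log2 change 1.34, but 0.41 on its second probe set), rose by 2.78 with Brg1sh_3364 against 0.25 and 0.98 (2.54e-06), Cntln, a centrosomal protein gene, by 2.36 against 0.36 and 0.93 (3.83e-06), and Bank1, a B cell adaptor gene, by 2.03 against 0.60 and 0.98 (4.09e-05). Ly75, an endocytic receptor gene, rose by 0.24 with Brg1sh_3364 and fell by 0.97 and 0.98 with the other two (5.89e-06). Eif2s3y rose by 1.30, 4.37 and 2.99 with Brg1sh_3232, Brg1sh_3364 and Brg1sh_4935 (2.64e-05). With hairpin means as replicates, the mean calls of Lrrk2 (0.211), Cntln (0.155), Bank1 (0.0651) and Ly75 (0.334) were lost.

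Between pairs of hairpins, 1925 genes differed for Brg1sh_3364 against Brg1sh_3232 (1159 higher and 766 lower with Brg1sh_3364). For Brg1sh_4935 against Brg1sh_3364 the number was 1518 (618 higher and 900 lower with Brg1sh_4935), and for Brg1sh_4935 against Brg1sh_3232 it was 204 (122 and 82, or 136 and 154 with arrays centred on their medians). Each hairpin had 2 arrays, and the counts depend on single ones. Without Brg1sh_3364 replicate 1 or 2, the F test called 677 or 734 genes, Brg1sh_3364 against Brg1sh_3232 gave 702 or 904, and Brg1sh_4935 against Brg1sh_3364 gave 559 or 649. Without Brg1sh_4935 replicate 1 or 2, the F test called 997 or 990 and Brg1sh_4935 against Brg1sh_3364 gave 496 or 486. Without Brg1sh_3232 replicate 1 or 2, Brg1sh_3364 against Brg1sh_3232 gave 1114 or 1147. The count of 204 was the least stable, at 19 and 65 without Brg1sh_3232 replicates 1 and 2, 80 without either array of Brg1sh_3364, and 8 and 10 without Brg1sh_4935 replicates 1 and 2. It was 359, 116 and 467 without control replicates 1, 2 and 3, which enter through the shared spread.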

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

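The test of Smarca4 depth was chosen only after the result was seen. Results stand here because hairpins against the same target differed by a direct test, or because signal lay in rows outside the gene comparisons. By the F test 2086 genes differed among the hairpins. In pairs, 1925 genes differed between Brg1sh_3364 and Brg1sh_3232, 1518 between Brg1sh_4935 and Brg1sh_3364, and 204 between Brg1sh_4935 and Brg1sh_3232. By camera at the preset correlation, 33 of 69 list shifts differed between 2 hairpins, and 0 with an estimated correlation (lowest adjusted p = 0.326).

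Brg1sh_3364 stood farthest from the other two in 1273 of the 2086 genes. A different depth of Smarca4 loss was not seen in the probe signal. Smarca4 with Brg1sh_3364 minus the mean of the other two was 0.034 on the log2 scale (95% interval -0.105 to 0.173). That interval lies inside a margin of 0.25, but the margin was set after Smarca4 was known, so it is no independent test. The same response at a larger or smaller size is argued against as the whole cause: among genes that differed between Brg1sh_3364 and Brg1sh_4935, 40.8% of differences had the sign of Brg1sh_3232 against control, and 56.9% in the comparison with Brg1sh_3232 and Brg1sh_4935 exchanged. Effects of the hairpin sequence on other transcripts, differences in Brg1 protein and separate histories of the transduced cultures stay open, and no table here tests them. Without Brg1sh_3364 replicate 1 the F test called 677 genes and without its replicate 2 it called 734, and the count without 1 array ranged from 677 to 2521.

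Of 121 named genes, 64 differed among the hairpins by the F test, against 10.5% of all genes. Of the 64, 6 were named for their F test p, and most named genes were chosen by size of change or smallest p on these same arrays. The share is therefore no test. The values that follow are the highest minus the lowest hairpin log2 change. Differences were 3.07 for Eif2s3y, 2.53 for Lrrk2, 2.43 for Prg2, 2.42 for Car4, 2.17 for Eya1 and 2.01 for Cntln. They were 1.74 for Mc5r, 1.56 for C3ar1, 1.51 for Cd200r3, 1.49 for F2rl2, 1.43 for Bank1, 1.22 for Ly75, 1.10 for Lgmn, 1.10 for Cd200r4, 1.09 for Atp1b1 and 1.04 for Itgax. Other strongly moved genes had 0.98 for Serpinb10, 0.82 for Angpt1, 0.69 for Muc13, 0.60 for Cnn3 and 0.45 for Hdc.

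Among leukaemia and macrophage genes the difference was 1.15 for Ikzf2, 0.75 for Myc, 0.71 for Cx3cr1, 0.67 for Mpeg1, 0.61 for Cd14 and 0.40 for Csf1r. Neutrophil genes gave 1.20 for Padi4, 0.87 for Cst7, 0.69 for Mpo, 0.63 for Prtn3, 0.59 for Trem1, 0.54 for Mmp9 and 0.48 for Cebpa. Growth and cell cycle genes gave 0.61 for Phgdh, 0.56 for Ccng2, 0.51 for Cdkn2b, 0.50 for Mybbp1a, 0.39 for Rrs1, 0.34 for Psat1, 0.26 for Mthfd1, 0.25 for Cdc25a, 0.23 for Ttk, 0.21 for Cdk1 and 0.21 for Tyms. Glycolysis genes gave 1.23 for Slc2a3, 0.84 for Aldoc and 0.36 for Slc16a3.

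Interferon and antigen presentation genes gave 1.34 for Usp18, 0.60 for Oasl2, 0.60 for H2-Ab1, 0.48 for Irf7, 0.39 for Cd74 and 0.36 for Irf9. Stress and inflammation genes gave 0.56 for Sesn1, 0.33 for Stc2, 0.28 for Bid and 0.23 for Tnfaip3. The lysosome list's Mitf gave 0.58. Markers of other blood cells gave 1.42 for Il7r, 0.64 for Cd79b, 0.52 for Mcpt8, 0.42 for Klrd1 and 0.28 for Id2.

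Of 13120 rows without a single gene symbol, 1362 were called in the mean contrast when every row was tested (10.4%, against 22.4% of named rows). Of these 804 rose and 558 fell, and 59 changed at least 2-fold.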

How the results depend on the processing

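The exact permutation of list means was chosen after seeing the data; all other alternatives were fixed before. No called list and none of the named genes called changed direction under the alternatives run for them, but which of rises and falls outnumbered the other was not stable, and medians of lists that were not called crossed 0. Rises outnumbered falls for the mean contrast without control replicate 2 (2489 and 2451), for Brg1sh_3232 without its replicate 1 (1701 and 1481) and for Brg1sh_4935 without its replicate 2 (1361 and 1346). They did so at 2-fold or more for these comparisons too, and falls outnumbered rises for Brg1sh_3364 with both other scalings. The near-equal split of genes shared by all 3 hairpins turned under several settings, as to 1263 and 1255 after a further quantile normalization. Smarca4 stayed called under every alternative run for it, between -1.06 with arrays centred on their medians and -0.98 without Brg1sh_3232 replicate 1. Groups of 2 or 3 arrays and the lack of signal-over-background values limit what small changes can be seen. The cause of each shift below was not tested, except that a stricter threshold lowers a count by construction.

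The count for the mean contrast was 2816 with the 3 hairpin means as replicates (2803 of the same genes) and 2557 with the hairpin as a random block (all 2557 the same genes; consensus correlation 0.289). Brg1sh_3232 fitted with the control alone called 2475 genes. At 2-fold or more the counts were 195 for the mean contrast, 162, 283 and 264 for Brg1sh_3232, Brg1sh_3364 and Brg1sh_4935, and 95 for all 3 the same way. They were 59 for Brg1sh_3232 against Brg1sh_3364, 17 for Brg1sh_3232 against Brg1sh_4935, 87 for Brg1sh_3364 against Brg1sh_4935 and 116 for the F test. At an adjusted p below 0.01, Brg1sh_3232, Brg1sh_3364 and Brg1sh_4935 called 2380, 3246 and 2813 genes, 1374 were the same way in all 3, the pairs differed in 759, 25 and 637 in the order above, and the F test called 775. Brg1sh_3232 and Brg1sh_4935 differed in 310 genes after a further quantile normalization, 394 with dim genes left out, 349 with array weights and 18 over every row of the deposited values. Brg1sh_3364 and Brg1sh_4935 differed in 2363 with array weights and 840 over every row, where the F test called 1134.

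Deviations of same-numbered arrays correlated between -0.072 and 0.249 over 12 pairs, 2 of them above 0.1. Those 2 were Brg1sh_3232 replicates 1 and 2 with the same-numbered controls (0.19 and 0.249), so pairing there cannot be excluded. The others lay between -0.072 and 0.028. Pairs of hairpins gave the same value for both numbers, since deviations in a group of 2 mirror each other. With the replicate block the mean contrast called 4712 genes and Brg1sh_3232 and Brg1sh_4935 differed in 382, and Ccl17 lost its call (adjusted p = 0.0924); no other named gene or list did.

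Leaving out 1 array at a time gave 4705 to 5407 genes for the mean contrast, 2473 to 4136 for Brg1sh_3232, 3424 to 5052 for Brg1sh_3364 and 2673 to 4292 for Brg1sh_4935. It gave 1648 to 2412 for all 3 the same way, 677 to 2521 for the F test, 702 to 2213 for Brg1sh_3232 against Brg1sh_3364, 8 to 467 for Brg1sh_3232 against Brg1sh_4935 and 486 to 1830 for Brg1sh_3364 against Brg1sh_4935. A hairpin left with 1 array is assumed to vary like the other groups.

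Of the 23 lists, 0 were called with an estimated correlation, 17 by fry and 18 by exact permutation, and 14 to 15 with 1 array left out. The permutation, over 84 splits, has a smallest p of 0.0119, reached by 16 lists and also by 262 of 1000 random lists of 30 genes. It called the leukaemia, dendritic, erythroid and megakaryocyte, and mast cell lists (adjusted p = 0.0171, 0.0304, 0.0171 and 0.0171), and lost the late neutrophil list. Lymphoid markers were called with dim genes left out (adjusted p = 0.0274, otherwise 0.0576 to 0.997). The random block was not run for lists, since camera takes none. Of 120 named genes besides Smarca4, 21 lost their call with hairpin means as replicates, 20 with the random block (the same genes except Cd14) and 12 without a hairpin term. Myb was called with trended robust eBayes (adjusted p = 0.0253).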

Other observations

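The tests of gene families, of Y-linked genes and of Xist were chosen only after the results were seen. Gene families were formed from symbols that share their letters, 437 in all; 45 were called by camera at the preset correlation and 0 with an estimated correlation (adjusted p = 0.694 for each family named here). Those named were picked from the 45 after their values were seen. Most measured genes of the mitochondrial ribosome fell: 32 of 48 with the stem Mrpl fell and 2 rose, and 25 of 29 with the stem Mrps fell and 0 rose. Mrpl19 fell by 0.60 (SE 0.04) and Mrps22 by 0.62 (SE 0.07). Of 14 Timm genes, for import into mitochondria, 11 fell and 0 rose, with Timm8a1 down by 1.14 (SE 0.12) and Timm50 by 0.54 (SE 0.04). Of 19 nucleoporin genes 16 fell and 0 rose, among them Nup107 by 0.64 (SE 0.07) and Nup43 by 0.62 (SE 0.06). All 7 Gstm genes, glutathione transferases, fell, with Gstm1 down by 0.74 (SE 0.07); their sequences are similar, and probes shared between them were not examined.

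In other families most of the called members rose. Of 12 annexin genes, for calcium-dependent membrane binding, 8 rose and 0 fell, with Anxa4 up by 1.17 (SE 0.07) and Anxa11 by 0.44 (SE 0.04). Of 8 interferon regulatory factor genes 5 rose and 0 fell, and Irf5, outside the fixed lists, rose by 1.34 (SE 0.08). Of 18 Kdm genes, most of them histone demethylases, 11 rose and 1 fell, with Kdm7a up by 0.69 (SE 0.06) and Kdm6b by 0.48 (SE 0.05). Of 8 Ms4a genes 5 rose and 0 fell. The median of each of these families kept its sign under both other scalings. The named members had all 6 knockdown arrays on one side of all 3 controls, and they were chosen after their values were seen.

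The Y-linked genes Eif2s3y, Kdm5d and Uty were higher in all 3 knockdown groups. Kdm5d rose by 0.63 (SE 0.07, adjusted p = 0.000178), Uty by 0.51 (SE 0.08, adjusted p = 0.00143) and Eif2s3y by 2.89 (SE 0.09), whereas the X-linked Eif2s3x fell by 0.19 (SE 0.04, adjusted p = 0.00345). The Y-linked Usp9y, Zfy1, Zfy2, Sry and Uba1y were not called, with log2 changes from -0.06 for Uba1y to 0.13 for Zfy2. Usp9y, Zfy1 and Zfy2 stood at percentiles 3.3, 8.4 and 0.5 of gene level, where a difference may not show. A lower share of cells with a Y chromosome in the control arrays is argued against as the whole cause for Eif2s3y. Its rise exceeded the mean of Kdm5d and Uty by 2.317 (SE 0.103). Its control level was low, at 4.91 against 9.13 for Kdm5d and 9.80 for Uty. Such a share may account for Kdm5d and Uty, which differed from each other by 0.125 (SE 0.108). It may also add to the Eif2s3y rise. Female cells that express Xist, mixed into the controls, are argued against only weakly. Xist differed by -0.004, control minus knockdown (95% interval -0.087 to 0.079). It stood at percentile 9.6 of gene level, and no array here showed a high signal by which to judge its probe set. Regulation of these genes by Brg1 and drift of separate cultures stay open, since the control arrays carry a line name of their own. That name does not bear on differences among the hairpins. Eif2s3y rose by 1.30, 4.37 and 2.99 with Brg1sh_3232, Brg1sh_3364 and Brg1sh_4935 (F test adjusted p = 2.64e-05). Kdm5d (0.475) and Uty (0.936) did not differ among them by the F test, and neither did Smarca4 (0.802).

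Ribosome biogenesis genes may follow Myc across the hairpins. Brg1sh_3364 had the lowest Myc, at -0.611 (SE 0.062) against the mean of the other two, and the list's mean was lower there by a difference of -0.223 (SE 0.07). This was the sign the hypothesis needed; the test was set before this difference was seen, but after Myc on each array and the list's overall shift were known. However, 3 hairpins are too few for a correlation, and other features of Brg1sh_3364 run with both. The controls showed no clear order: the list's mean was lowest in replicate 1 (10.98), where Myc was highest (12.47), and highest in replicate 3 (11.20), where Myc was 12.39. Replicate 2 had the lowest Myc (12.34) and a list mean between those of the others. That spread of the list is about as large as its difference for Brg1sh_3364.

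Other splits of the 9 arrays into groups of the same sizes were tried, 100 in all. For the number of genes in the mean contrast, 1 of 100 splits, the real one, gave as many: the real count was 5635 and the highest other 3517. Of the others, 2 kept the real control arrays together and gave 3492 and 3517. The rest mixed control and knockdown arrays, which puts the difference between them into the spread, and their highest count was 24. Such splits do not test chance between cultures: arrays that resemble each other by culture would also rank the real split first. The rank of the gene count therefore concerns only a random assignment of labels to these 9 arrays. For the number of lists, 6 of 100 splits gave at least the real 15, the highest other being 16 and the median of the others 9, so chance cannot be excluded for that number. Of the 6, 2 besides the real one kept the real control arrays together and so measured the same difference; leaving these out, it was 4 of 98 splits.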
